A study of Mus musculus with 9 samples.

How the data were processed

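RNA was sequenced from F4/80 and CD11b double-positive cells sorted from mouse visceral adipose tissue, in 5 libraries of Nucb2-deficient mice and 4 of wild-type mice. Per the labels' protocols, messenger RNA was selected on oligo-dT beads and made into strand-specific libraries by the dUTP method. The submitters' processing notes name CASAVA 1.8.2, HISAT, Partek, DESeq2 and the mm10 build, without saying what each was used for. The gene annotation, the counting of reads shared between genes, the use of strand in counting and the filter on genes are not given in the sources used here.

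The deposited values are a signal per gene and library: read counts divided by 1 factor per library, on a linear scale, with each value under 1 set to 1. The deposited table held 14905 genes, all 9 columns matched a library by name, and the lowest mean over libraries was 5.09, so genes of low mean had been left out. That the values are counts over size factors was read from the values themselves. In each library 99.4% to 99.7% of the values above 1 were whole multiples of 1 step, within a tolerance of 0.1 of a step, and median-ratio factors recomputed on the deposited values lay between 1.0141 and 1.0171. The step gave totals of 51148956 to 85200104 reads. In 6 libraries the step was under 1, so the floor holds libraries with 0 reads and with 1 read of a gene; in the other 3 it holds 0 reads only. Between 6.3% and 9.9% of the genes of a library were at the floor. Because of this floor no count-model test was used, and a fold against a group at the floor in each of its libraries is given as a bound from 3 reads per library, which covers counting error only.

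The main test was limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus a pseudocount of 1, with a mean-variance trend, all 9 libraries, genotype as the only term, and Benjamini-Hochberg adjustment over 14905 genes at 0.05. Fold changes are on that scale, which understates changes of low genes. The planned filter, a value of at least 1 in at least 4 libraries, removed 0 genes since no value is under 1. The 35 gene lists, fixed before the data were examined, held 18 of macrophage programmes, 4 of quality or chromosome position and 13 of other cell types that the sort could hold. They were tested with camera at an inter-gene correlation of 0.01 on the same fit, and again with an estimated correlation and with fry; members were also counted after adjustment over the list alone. The genes named are Nucb2, then the 12 largest increases and 12 largest decreases among genes past the threshold whose mean was at or above the median over genes, 648.6, and whose symbol is not a predicted name, and up to 4 members of each list with the smallest p. Genes outside that rule (Pira4, Pira6, Pira11, Gm14548, H2-DMb2, Tnf, Il6, Il1b, Adgre1, Nnt, Ide, Entpd4, Nos2, Ric3, Adipoq, Pirb, Kit, Mcpt4, Hdc, Ms4a2, Atp6v1c1 and Rhpn2) were picked after their values were seen. A few genes that the rule takes are not reported here. Single values were tested with exact permutation tests in SciPy 1.17.1 under Python 3.11.15. Positions come from GENCODE release M21 on GRCm38, the assembly that mm10 names, matched by symbol for 14369 genes (96.4%).

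The code was tested on simulated data with the 14905 genes' own means, a spread set by the mean alone, and genes independent of each other. The 200 genes changed by known folds were not drawn from genes of low mean, and a list of 20 further genes was raised. Of genes changed 1.5, 2, 4 and 8 fold, 40%, 62%, 88% and 98% were recovered (50 genes each), and 3 of 159 calls were unchanged genes. These shares do not describe low, unusually variable or correlated genes. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, no filter or a mean of at least 10, median-ratio and quantile scaling, array weights, robust moderation, replicate number as a block, and each library left out in turn. Added after seeing the data were limma-voom on the reads worked out from the steps, depth class as a term, the 6 deeper libraries alone, and a filter on values above 1 in at least 4 libraries. Figures were drawn with matplotlib 3.10.9.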

Results

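Gene expression was measured by RNA sequencing in macrophages taken from the visceral fat of mice, as cells positive for both F4/80 and CD11b in a fluorescence-activated sort. F4/80 (the product of Adgre1) and CD11b (the product of Itgam) are surface proteins that macrophages carry together. The design held 5 libraries from mice with both copies of Nucb2 disrupted (KO) and 4 from wild-type mice (WT), all on a C57BL/6 background. Nucb2 encodes nucleobindin-2, a calcium-binding protein from which the peptide nesfatin-1 is cut. The series title places the work in obesity and insulin sensitivity; the diet of these mice is not given in the sample labels. The deposited table held normalized read counts for 14905 genes, with a floor of 1. Reads worked out from the spacing of the values came to between 74937721 and 85200104 in 6 libraries (KO replicates 1 to 4, WT replicates 1 and 2) and between 51148956 and 55004978 in the other 3 (KO replicate 5, WT replicates 3 and 4). The labels number the libraries of each group as replicates and do not say that each came from its own mouse, so p-values measure the spread between these libraries, which may be partly technical. Among the 5247 genes with a mean of 1000 to 10000 reads, the median coefficient of variation among the KO libraries was 16.8%, where counting error alone would give 2%. Among the 2102 genes with 20 to 100 reads it was 93.9%, where it would give 14.6%.

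Nucb2 was lower in each of the 5 KO libraries than in any WT library. Its normalized count was 1500 ± 219 (SD, n = 5) in KO, between 1165 and 1752, and 4313 ± 791 (SD, n = 4) in WT, between 3311 and 5233. The KO mean was 34.8% of the WT mean, so the transcript was reduced and still detected in the KO libraries. On the log2 scale the difference was -1.52 (SE 0.17; limma, adjusted p = 0.00054), and an exact two-sided permutation test gave p = 0.0159, the smallest that splits of 9 libraries into 5 and 4 allow. Within the 6 deeper libraries the difference was -1.61, which did not pass there (adjusted p = 0.116), and within the 3 shallower ones it was -1.25. With the replicate number as a block, which drops KO replicate 5, it was -1.58 (adjusted p = 0.0515). The gene lies on the plus strand of chromosome 7 from 116504369 to 116540584 (mm10). The table gives 1 value per gene, so it does not show which exons the remaining reads covered.

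The comparison of KO with WT asked which transcripts of these macrophages differ when Nucb2 is lost. Apart from Nucb2 itself, the libraries separated most sharply on a small set of genes that included Wdfy1, an endosomal adaptor protein, Dpys, an enzyme of pyrimidine breakdown, and Pira1, one of the Pira genes, which encode activating immunoglobulin-like receptors of myeloid cells. Wdfy1 stood at 3174 ± 397 normalized counts in KO and 751 ± 221 in WT (SD, n = 5 and 4; fold 4.36, limma adjusted p = 0.00036). Dpys stood at 1933 ± 351 in KO and 348 ± 110 in WT (fold 5.66, limma adjusted p = 0.00039). Smaller differences that passed included Cxcl1, which was higher in KO, and H2-Aa, Cd72 and Clec7a, which were lower. In all, 46 of 14905 genes passed an adjusted p of 0.05 in limma, 27 higher and 19 lower in KO, and 1363 had an unadjusted p under 0.05. In each of the 46 the KO and WT ranges did not overlap, as they did not in 469 genes of the table; chance alone separates the ranges of 1.59% of genes. The count depended on single libraries: it was 8, 14, 5, 8 and 9 without KO replicates 1, 2, 3, 4 and 5, and 38, 10, 18 and 19 without WT replicates 1, 2, 3 and 4. It was 33 with the depth class of the library as a term, 0 in the 6 deeper libraries alone (1039 at an unadjusted p under 0.05), and 32 with limma-voom, where 12 were higher and 20 lower.

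**Figure D1:**
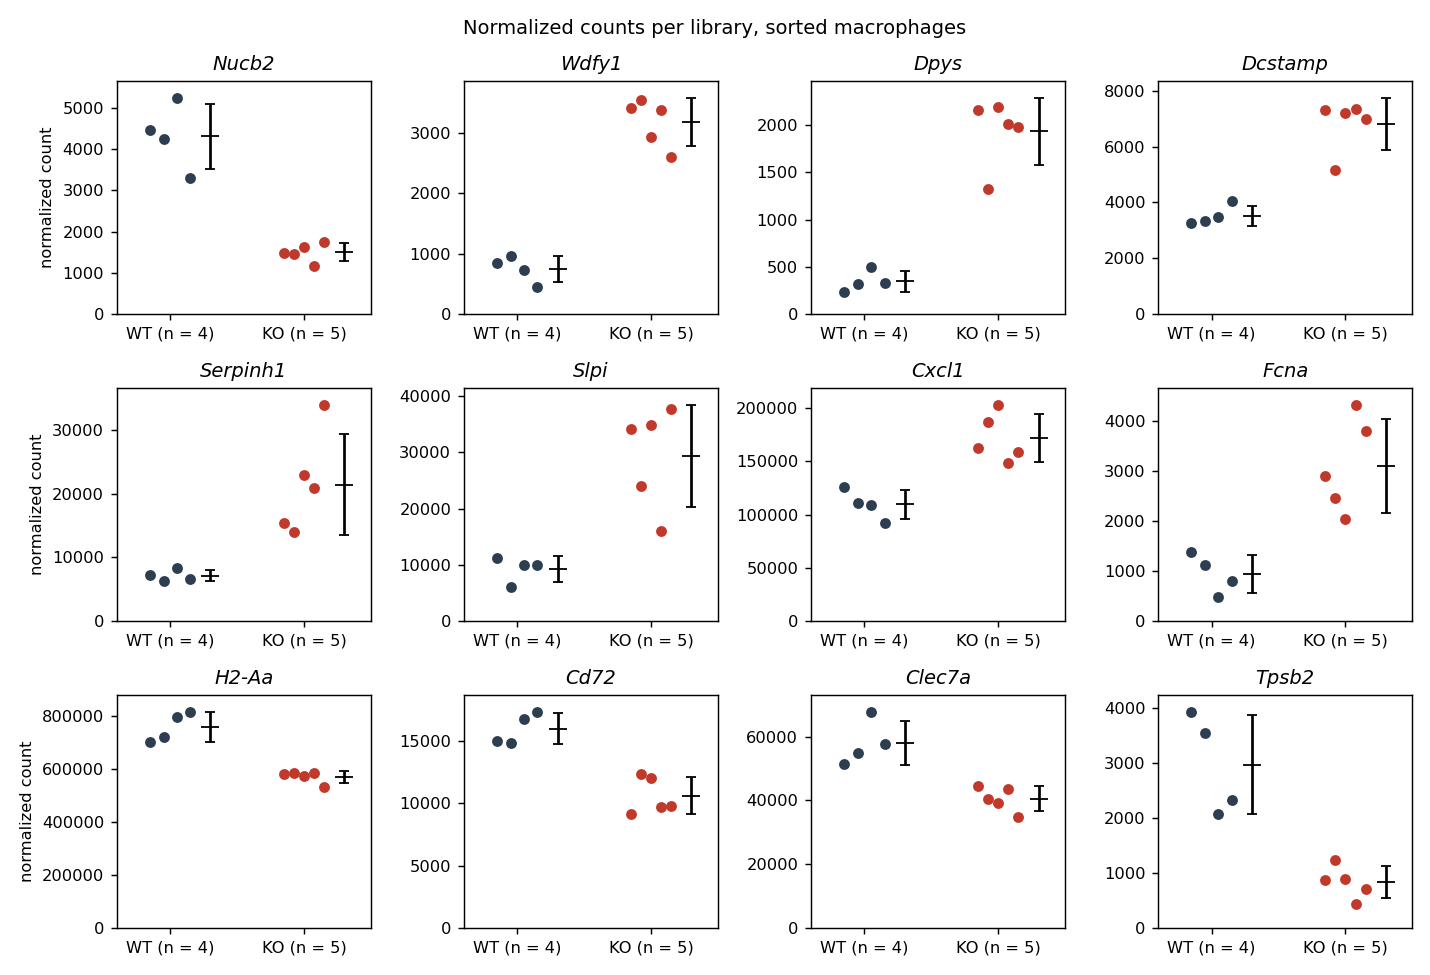
Normalized counts of 12 genes in each library, WT (dark, n = 4) and KO (red, n = 5), with the mean and SD beside the points; each vertical axis is linear and starts at 0. Nucb2, H2-Aa, Cd72, Clec7a and Tpsb2 lie lower in each KO library than in any WT library, and the other 7 genes lie higher; KO replicate 2 has the lowest KO value of both Dpys (1326) and Dcstamp (5174).

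Genes higher in KO had varied products. Slpi, a secreted inhibitor of leukocyte proteases, had 29319 ± 9046 normalized counts in KO and 9283 ± 2270 in WT (SD, n = 5 and 4; fold 3.10, limma adjusted p = 0.0038). Serpinh1, the collagen chaperone of the endoplasmic reticulum, had 21377 ± 7885 against 7118 ± 853 (fold 2.87, adjusted p = 0.0023). Fcna, which encodes the lectin ficolin A, had 3098 ± 941 against 944 ± 385, and Ednrb, an endothelin receptor, had 7942 ± 1815 against 3113 ± 894. Tmem184c rose by 1.14 on the log2 scale. Ackr1, a chemokine-binding receptor of venular endothelium and red cells, and Selp, which encodes P-selectin of endothelium and platelets, rose by 2.09 and 1.92. The endothelial list had a median log2 difference of 1.29 in the same libraries. Of its 12 members 0 passed over all genes, and its camera adjusted p was 0.12 with an estimated correlation.

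Among called genes lower in KO with a mean of at least 648.6 normalized counts and a symbol that is not a predicted name, the mast cell proteases Cpa3, Tpsb2 and Cma1 differed most, by -2.42, -1.87 and -1.64 on the log2 scale (limma adjusted p = 0.022, 0.0092 and 0.014). Ehf, an epithelial transcription factor, differed by -1.63. Several other genes were lower by a smaller amount. Clec7a, which encodes the fungal glucan receptor dectin-1, had 40508 ± 3879 normalized counts in KO and 57970 ± 7007 in WT (SD, n = 5 and 4; limma adjusted p = 0.022). Cd72, a C-type lectin of B cells and macrophages, had 10604 ± 1473 against 15967 ± 1242, and Aif1, which encodes the macrophage protein IBA1, had 18736 ± 1171 against 30567 ± 7775. The gelatinase gene Mmp2 differed by -0.72 and Tnfaip6, whose product binds hyaluronan, by -0.51. Rn45s, the precursor of ribosomal RNA, took 1.97% ± 0.13 of the normalized counts in KO and 2.98% ± 0.38 in WT (SD, n = 5 and 4). Its log2 difference was -0.67 (limma adjusted p = 0.0020). Quantile normalization, which gives genes of equal rank equal values, set that difference to 0. The share of Rn45s separated the groups completely, at 1.84% to 2.16% in KO libraries and 2.64% to 3.54% in WT libraries. Its cause was not tested, and one tied to RNA or library preparation could not be told apart from genotype, here or for other calls.

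Of the 6 Pira genes measured, 4 passed, Pira1 and Pira7 higher and Pira2 and Pira11 lower in KO, and Pira4 and Pira6 did not (limma adjusted p = 0.40 and 0.25). Pira2 and Pira7 passed in 0 of the 9 fits that left out 1 library. Pira1 stood at 1621 ± 777 normalized counts in KO and 19.9 ± 18.5 in WT, and Pira7 at 1031 ± 254 in KO and 366 ± 111 in WT (SD, n = 5 and 4). Pira2, on chromosome 7 from 3836812 to 3845051, was lower, with 1449 ± 327 in KO and 2987 ± 650 in WT. A pair of further genes, picked out after their values were seen, were close to the floor in KO: Pira11 had 2.25 ± 2.65 against 308 ± 130, and Gm14548, on chromosome 7 from 3884242 to 3898120, had 3.46 ± 3.99 against 1364 ± 128. The sum over the 6 Pira genes was 8129 ± 1677 in KO and 8509 ± 1054 in WT. These genes are near-identical copies, and the way reads were divided among copies is not stated, so each single value is uncertain.

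**Figure D2:**
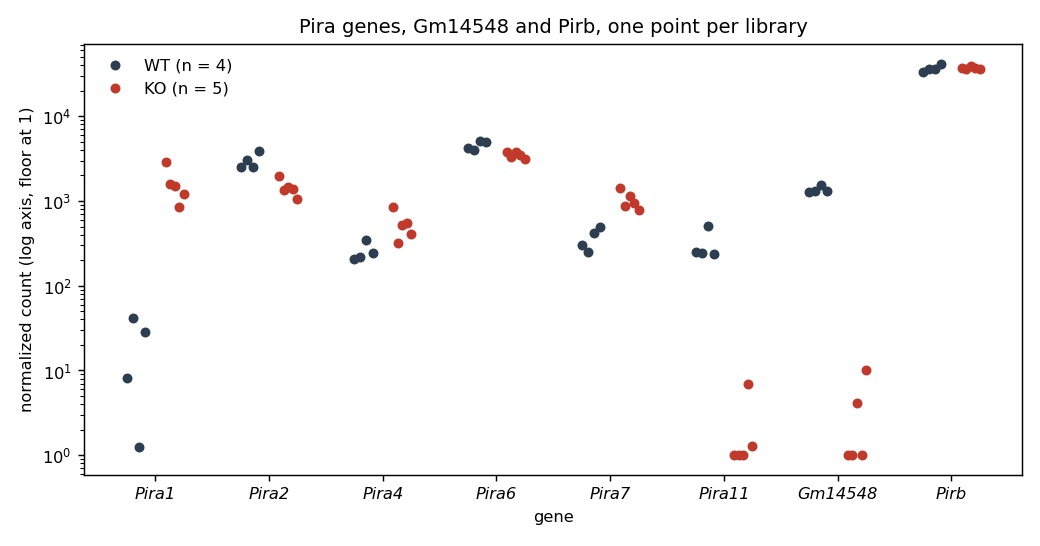
Normalized counts of the 6 Pira genes, Gm14548 and Pirb in each library on a logarithmic axis, WT dark (n = 4) and KO red (n = 5), where 1 is the floor of the table. Pira1 lies between 857 and 2908 in KO and at 41.5 or less in WT, while Pira11 and Gm14548 show the opposite pattern.

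Genes of antigen presentation on MHC class II were lower in KO as a group in camera at the preset correlation. With an estimated correlation the list did not pass (camera adjusted p = 0.12). H2-Aa, an MHC class II chain, had 571120 ± 21990 normalized counts in KO and 759810 ± 56075 in WT (SD, n = 5 and 4; log2 difference -0.41, limma adjusted p = 0.011), and H2-Eb1 had 336330 ± 11208 against 447460 ± 52649 (-0.40, adjusted p = 0.028). Of the 15 measured members, 2 fell, 0 rose and 13 did not pass over all genes; adjusted over the list alone, 9 were lower and 1, H2-DMb2, was higher. The invariant chain gene Cd74 (-0.31, adjusted p = 0.052) and H2-Ab1 (-0.36, adjusted p = 0.054) lay just outside the threshold. The list fell in camera (adjusted p = 2.6e-09; median log2 difference -0.32), with adjusted p = 0.12 with an estimated correlation, and in the 6 deeper libraries its median was -0.17 (adjusted p = 0.0046). In the same KO libraries the median log2 differences of mesothelial, endothelial and mast cell, eosinophil and basophil markers were 1.57, 1.29 and -1.32. These lists did not pass with an estimated correlation either.

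Macrophage identity genes were lower as a list in camera at the preset correlation, with a median log2 difference of only -0.03. Of the 24 members 14 lay below 0 and 10 above, without a call for a single member over all genes. Lyve1, one of those above, differed by 1.23 on the log2 scale (limma adjusted p = 0.13). C1qa, a chain of complement C1q, had 25246 ± 3932 normalized counts in KO and 35388 ± 3044 in WT (SD, n = 5 and 4; limma adjusted p = 0.067), and the Fc receptor gene Fcgr1 had 10015 ± 1208 against 14253 ± 2765 (adjusted p = 0.12). Of 24 members, 2 were higher and 9 lower adjusted over the list alone; camera gave adjusted p = 0.0062 (0.25 with an estimated correlation), 0.092 without KO replicate 5, 0.075 without WT replicate 4 and 0.22 in the 6 deeper libraries. The list of dissociation-induced genes had a median log2 difference of 0.23 in the same libraries. It did not pass with an estimated correlation. Among 30 genes of lipid-associated macrophages and lysosomes, Dcstamp, a fusion protein of osteoclasts and giant cells, rose (6804 ± 922 against 3532 ± 356, limma adjusted p = 0.0033) and 29 did not pass. Adjusted over the list alone, Dcstamp was higher and the fatty acid carrier Fabp5 lower (1 each). That list as a whole was lower in camera (adjusted p = 3.0e-04), with adjusted p = 0.46 with an estimated correlation, 0.081 without WT replicate 4 and 0.14 in the 6 deeper libraries. The nuclear genes of oxidative phosphorylation, such as Atp5o (-0.24, adjusted p = 0.26) and Cycs (-0.25, adjusted p = 0.30), had 0 of 28 members past the test in either adjustment and were lower as a list (camera adjusted p = 1.2e-05, 0.26 with an estimated correlation, 0.14 in the 6 deeper libraries). Calcium-handling genes, the class to which Nucb2 belongs by function, were higher as a list of 23 (camera adjusted p = 0.011, 0.12 with an estimated correlation, 0.057 without WT replicate 4, 0.14 in the 6 deeper libraries). The only member past the threshold adjusted over the list alone was Rcn3, a calcium-binding protein of the endoplasmic reticulum (7706 ± 1341 against 4996 ± 779, adjusted p = 0.082 over all genes).

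Inflammatory cytokine genes showed no common direction. Cxcl1, a neutrophil attractant, rose to 171780 ± 22472 normalized counts in KO from 109610 ± 13908 in WT (SD, n = 5 and 4; fold 1.57, limma adjusted p = 0.0096), and the other 24 members did not pass, over all genes or adjusted over the list alone. Tnf stood at 10394 ± 1414 in KO and 11815 ± 2542 in WT, Il6 at 11800 ± 1875 and 11598 ± 2703, and Il1b at 86563 ± 12744 and 83121 ± 6990, differences smaller than the spread between libraries. Camera gave adjusted p = 0.79 for the list, whose median and mean log2 differences were 0.05 and -0.16, and 0.78 for the 27 genes of the NF-kB pathway, of which Ier3 and Ikbkb were higher adjusted over the list alone (2 genes). The insulin, PI3K and mTOR list of 26 genes had camera adjusted p = 0.79, a median of -0.01 and a mean of 0.09. Of 25 alternative activation genes, 0 passed over all genes and 4 were higher adjusted over the list alone, among them the lectin genes Mgl2, Cd209f and Cd209g (camera adjusted p = 0.12, and 0.032 without WT replicate 1). Interferon response genes had 0 of 30 members past either test; the list was lower in camera (adjusted p = 0.023, 0.53 with an estimated correlation), with adjusted p = 0.82 without WT replicate 3 and the opposite direction in the 6 deeper libraries (adjusted p = 0.47).

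Markers of several other cell types differed between the groups in camera at the preset correlation. With an estimated correlation these lists did not pass. Of 12 measured genes of mast cells, eosinophils and basophils, 4 fell: Cpa3, Tpsb2, Cma1 and Fcer1a. Fcer1a was at the floor in each KO library and at 115 ± 83.3 normalized counts in WT (SD, n = 4), between 35.4 and 224. Its WT mean was 41.8 times a floor of 3 reads per KO library, a value that leaves out the spread between WT libraries. Adjusted over the list alone, 7 of the 12 were lower, and camera gave adjusted p = 2.2e-07 (0.12 with an estimated correlation). Of 10 mesothelial genes, 0 passed over all genes and 7 were higher adjusted over the list alone; Upk1b had 3586 ± 1583 in KO and 1070 ± 873 in WT (limma adjusted p = 0.10) and the list had camera adjusted p = 2.0e-08 (0.16 with an estimated correlation). Of 12 endothelial genes, 0 passed over all genes and 4 were higher adjusted over the list alone; Pecam1 had 1656 ± 586 against 601 ± 223 (limma adjusted p = 0.076) and Vwf 1176 ± 382 against 459 ± 123, with camera adjusted p = 7.9e-07 (0.12 with an estimated correlation). Peritoneal macrophage genes were higher, with Selp past the test and 4 of 14 higher adjusted over the list alone, Prg4 among them (2033 ± 692 against 756 ± 245; limma adjusted p = 0.052); camera gave adjusted p = 2.1e-04 (0.12 with an estimated correlation). Genes induced by tissue dissociation had 0 of 28 members past the test and 9 higher adjusted over the list alone; Fos had 82839 ± 12648 against 57087 ± 11218 (limma adjusted p = 0.089), and camera gave adjusted p = 7.9e-07 (0.25 with an estimated correlation, 0.14 in the 6 deeper libraries).

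In all, 14 of 34 testable lists passed in camera with a preset correlation of 0.01, 8 higher and 6 lower in KO, and 0 passed with an estimated correlation. The remaining lists higher in KO were neutrophil (camera adjusted p = 0.0070, 0.25 with an estimated correlation), monocyte (6.5e-04, 0.25 with an estimated correlation) and fibroblast genes (0.031, 0.53 with an estimated correlation, and 0.088, 0.074 and 0.48 without KO replicates 3, 4 and 5, and 0.080 and 0.78 without WT replicates 3 and 4). In the 6 deeper libraries 7 lists passed: MHC class II, mesothelial, endothelial, mast cell, peritoneal macrophage, neutrophil and monocyte genes; there the fibroblast list had the opposite direction (adjusted p = 0.16). The fibroblast list held 1 gene past the test over all genes, Mmp2, which fell. Mmp9, a member of the neutrophil list, had 433 ± 118 normalized counts in KO and 112 ± 14.5 in WT (SD, n = 5 and 4, limma adjusted p = 0.089). Among the 20 lists that did not pass, camera adjusted p lay between 0.094 and 0.998; they covered cytokines, NF-kB, alternative activation, insulin signalling, the inflammasome, endoplasmic reticulum stress, glycolysis, cholesterol synthesis and efflux, fatty acid oxidation, catecholamine handling, the cell cycle, sex-linked genes, neighbours of Nucb2 on chromosome 7, and markers of T, NK, B and dendritic cells, adipocytes, red cells and platelets. Leaving out 1 library brought 4 of them past it: cholesterol synthesis and the inflammasome without KO replicate 1 (adjusted p = 0.011 and 0.016), T cells without KO replicate 3 (0.026) and alternative activation without WT replicate 1 (0.032). The list of 15 mitochondrially encoded genes could not be tested, as 0 were in the table. In fry, 5 lists passed for a common direction, each just under the threshold. They were MHC class II genes (fry adjusted p = 0.049) and calcium-handling, endothelial, mast cell and peritoneal macrophage genes (0.045 each).

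**Figure D3:**
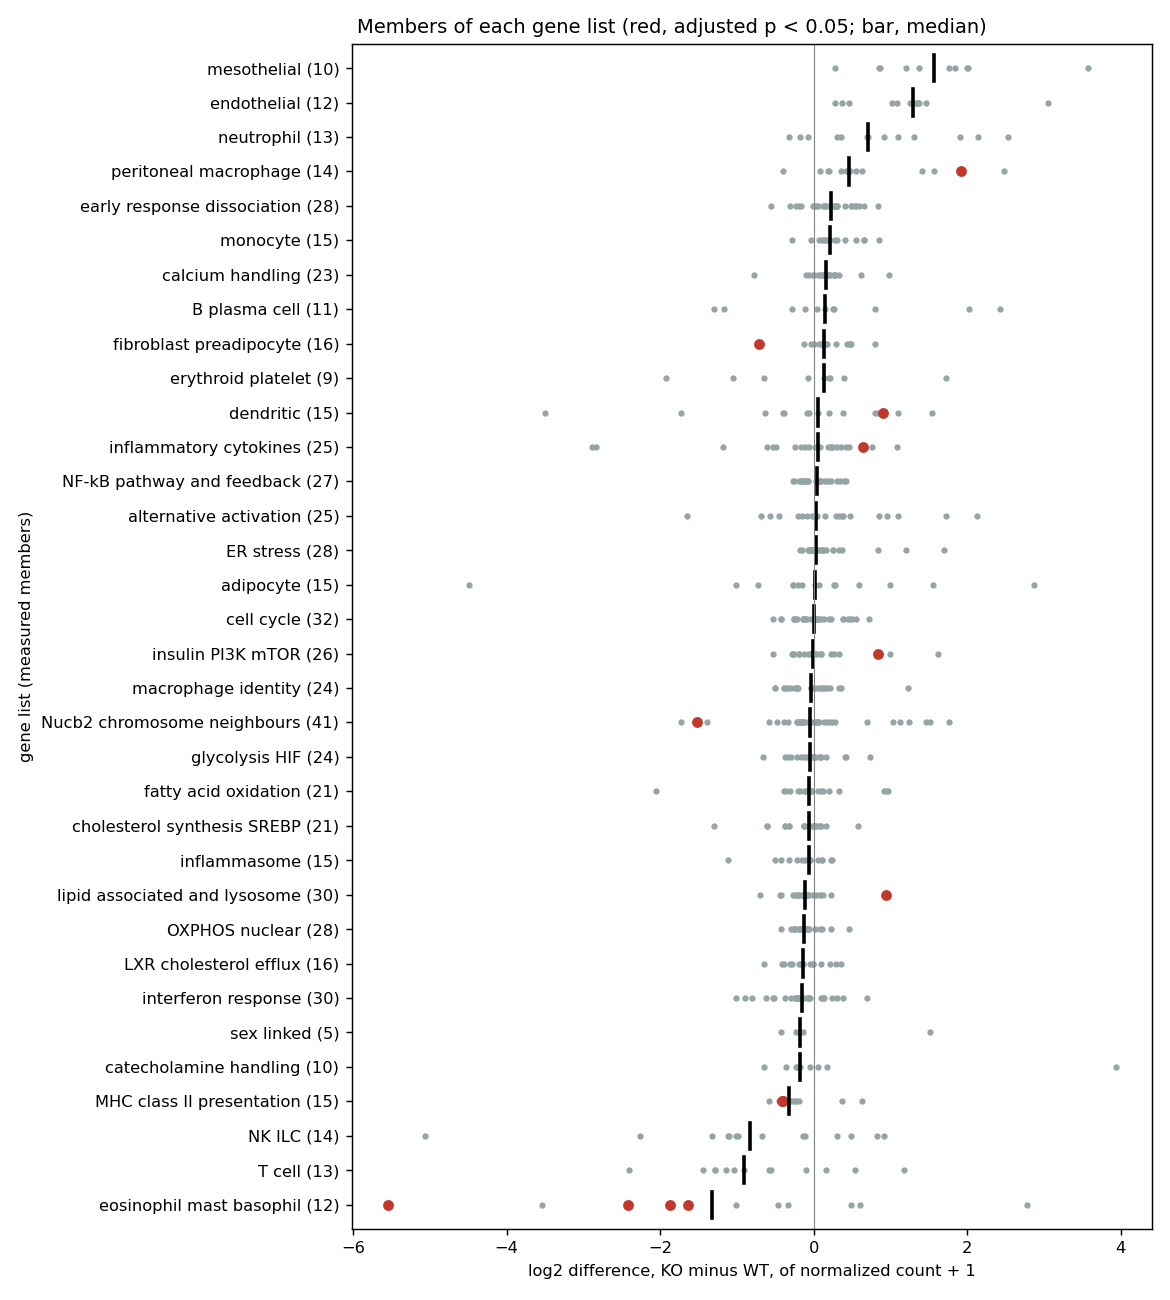
Log2 difference, KO minus WT, of each measured member of the 34 testable lists; red points passed an adjusted p of 0.05 over all genes, grey points did not, bars mark each list's median and the number of measured members stands beside the name. Mesothelial and endothelial medians lie at 1.57 and 1.29, the mast cell, eosinophil and basophil median at -1.32, and MHC class II members cluster at small negative values around -0.32.

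Across all genes the libraries differed about as much within a group as between groups. Correlations between libraries lay between 0.884 and 0.915, with a median of 0.906 within groups and 0.900 between groups; they are across genes, which are not independent replicates. The first principal component held 17.1% of the variance, and the KO libraries lay between 7.5 and 81.2 on it and the WT libraries between -94.2 and 0.1.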

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

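Of the tests in this part, those of mast cell, stromal and MHC class II genes and of neighbouring genes were chosen after the results were seen. The bounds for the Pira sum and for Nnt were set beforehand. The patterns that these bounds address, Pira calls in both directions and the difference in Wdfy1, are worded from the called genes. Nnt, Pira4, Pira6 and Pira11 are also named above as genes picked after their values were seen. These bounds thus do not make the tests independent of the results. A library far from the others of its group, by the gap to its neighbour over the group's range, was found in 11 of 168 groups of values examined, where chance gives about 1 in 20, or 8. Recovered reads were 51148956 in KO replicate 5 and 77813245 to 85200104 in the other KO libraries. KO replicate 2 had 1326 normalized counts of Dpys, against 1983 to 2187 in the other KO libraries, and 5174 of Dcstamp, against 6986 to 7346. KO replicate 5 had 532800 of H2-Aa (others 572660 to 585400) and 5536 of Pycard, the inflammasome adaptor gene (others 7107 to 7421). Single KO libraries also stood apart in Clec9a (1 in replicate 3, others 33.1 to 72.9), Mgl2 (21310 in replicate 4, others 18148 to 18804) and Ier3 (37080 in replicate 1, others 27312 to 29566). Among WT libraries, Ackr1 was 382.8 in replicate 2 (others 177 to 191), Jun 4154 in replicate 1 (others 2628 to 2764) and Gsn 154400 in replicate 4 (others 191080 to 199160).

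Inherited variants that travelled with the genotype stay open, beside loss of Nucb2, for several of the differences, in Wdfy1, the Pira genes, Dpys and Dcstamp. Neighbouring called genes with starts less than 1 Mb apart numbered 5, among 42 called genes with a position, against a median of 1 and a 95th percentile of 4 in 10000 random draws (permutation p = 0.015). Variants in cis cannot be told apart from shared regulation by this count, because H2-Aa with H2-Eb1 and H2-Eb1 with Aif1 lie in the MHC region and Pira2 with Gm14548 in the Pira family. The other 2 pairs were Fcer1a with Ackr1, which went in opposite directions, and Dpys with Dcstamp, 0.02 Mb apart on chromosome 15. Dpys and Dcstamp were both lowest in the same KO library. Atp6v1c1, also on chromosome 15 (38661933 to 38692446), was called lower in KO (log2 difference -0.48, limma adjusted p = 0.014). Its start lay just beyond the 1 Mb limit from that of Dcstamp (39745930), so it was not counted. Reads moving between near-identical Pira copies cannot be told apart from a change in the genes: their sum differed by -0.08 on the log2 scale, under the bound of 0.3 set beforehand, but by -0.30, at that bound, with Gm14548, which was added after its values were seen (SD 0.28 among the KO libraries). A region carried along with the targeted locus cannot be told apart from none, since 1 of 116 genes within 10 Mb of Nucb2 was called, against 40 of 14252 elsewhere (Fisher's exact test, two-sided p = 0.283). Pira2 and Dpys lie outside that window. Called genes farther along chromosome 7 include Serpinh1 (99345376 to 99353239), Rhpn2 (35334170 to 35392289), Pira2 and Gm14548, so a wider region stays open. Pira1, Pira7 and Pira11 had no position and were not counted. A C57BL/6J against C57BL/6N difference, which is known to alter Nnt, also cannot be told apart from the genotype: Nnt differed by 0.69, between the bounds of 0.5 and 1 set beforehand.

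Mast cell genes were lower and endothelial and mesothelial genes higher in KO in camera at the preset correlation, in a fraction sorted for F4/80 and CD11b, a gate that should remove most such cells. With an estimated correlation these lists did not pass (adjusted p = 0.12, 0.12 and 0.16), and over all genes 4 of 12, 0 of 12 and 0 of 10 members did. The 8 mast cell markers had a median log2 difference of -1.87 (the same with Fcer1a at its bound), with 7 below 0. Fewer mast cells, or less RNA from them, in the KO fraction cannot be told apart from lower expression of these genes. This is because 4 of the 8 are the called genes that made the pattern. Of the 4 that were not called 3 were below 0: Kit, Mcpt4 and Hdc (-3.54, -1.87 and -1.01 on the log2 scale). These 3 were lower adjusted over the list alone and did not pass over all genes. The other, Ms4a2, differed by 0.61 and was close to the floor (mean 23.0 in KO and 2.83 in WT). Levels of the mast cell markers were low: Tpsb2 had 2969 normalized counts in WT, against 106110 for Adgre1. A common gain of stromal cells cannot be told apart from a gain of endothelial and mesothelial cells alone: the fibroblast median, 0.14, was 0.11 of the endothelial median of 1.29, but fibroblast markers stood at a median of 9325 normalized counts in WT, against 277 for endothelial ones, so a small added share would be hidden in them, and 13 of 16 were above 0. A change in the cells themselves between genotypes also stays open.

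MHC class II genes were lower in KO in camera at the preset correlation, and with an estimated correlation the list did not pass (adjusted p = 0.12). WT replicates 3 and 4 may carry part or most of the difference. Without the 3 shallower libraries the list's median was -0.17, against -0.32 over all 9, and its camera adjusted p was 0.0046 at the preset correlation. That fit rests on WT replicates 1 and 2 alone and was not repeated with an estimated correlation. It therefore cannot decide how much of the difference the other WT libraries carry. Relative to each gene's mean, the members' median log2 level lay between -0.18 and -0.09 in the deeper KO libraries, at -0.002 and 0.08 in the deeper WT libraries, and at 0.35 and 0.31 in WT replicates 3 and 4. Fewer dendritic or B cells cannot be told apart from lower expression per macrophage, because the dendritic and B cell medians were 0.05 and 0.14 with members going both ways (SD 1.25 in the wider list). Lower expression in macrophages of KO mice stays an untested hypothesis.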

How the results depend on the processing

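Limma-voom, depth class as a term, the 6 deeper libraries alone and the filter above 1 were chosen after the data were seen. Nucb2, the targeted gene, stayed lower under each alternative (log2 difference -1.42 to -1.64, adjusted p 0.00031 to 0.116); it did not pass with the replicate block (-1.58, adjusted p = 0.0515) or in the 6 deeper libraries (-1.61, adjusted p = 0.116), both with fewer libraries. Calls in all, higher and lower were 0, 0 and 0 in the 6 deeper libraries (1039 genes at an unadjusted p under 0.05 in limma). Leaving out 1 library gave 5 to 38 genes, 2 to 26 higher and 3 to 12 lower, and limma-voom gave 12 higher of 32, 29 of them shared with the main 46; the cause was not tested. The depth term kept 27 of the 46 among its 33 calls. Replicate numbers 1 to 4 are shared by KO and WT, and deviations of same-numbered libraries correlated at -0.053, 0.09, 0.004 and 0.062. KO replicates 2 and 4 correlated best with their own number and 1 and 3 did not. These weak correlations cannot decide whether the numbers pair the samples. With the replicate block, which drops KO replicate 5, limma called 0 genes, 0 higher and 0 lower (1104 at an unadjusted p under 0.05). Besides Nucb2, 28 named genes passed, of which Dpys and Wdfy1 passed in all 9 fits that left out 1 library and 26 were lost in 1 or more. Ackr1, Cd72, Clec7a, Cpa3, Ehf, Pira2, Pira7 and Tmem184c passed in 0 of these 9 fits. Rn45s turned to 0 (1.4e-15) under quantile normalization, which gives the most abundant rows of each library the same value, and the interferon and fibroblast lists turned direction in the 6 deeper libraries (adjusted p = 0.467 and 0.156; the cause was not tested). Lists past the threshold were 14, and 9 without WT replicate 4 (9 to 16 over libraries left out), 7 in the 6 deeper libraries, 0 with an estimated correlation and 5 with fry. The first component held 16.1% (quantile), 16.9% and 17.8% (pseudocounts 0.1 and 10) and 17.3% (mean of at least 10), against 17.1%. Of 1782 other values of named genes, 1486 kept direction and side of the threshold, 277 lost the call, 18 gained it and 1 turned; of 336 values of the 14 lists past the threshold 285 kept it, 49 lost it and 2 turned. Of 480 values of the other 20 lists 7 passed: alternative activation, endoplasmic reticulum stress and T cells under quantile normalization, and 4 with 1 library left out (cholesterol synthesis and inflammasome without KO replicate 1, T cells without KO replicate 3, alternative activation without WT replicate 1). Of 100 splits of the 9 libraries, 1, the real one, gave as many as 46 genes (highest other 6). That is the smallest share that 100 splits allow, and it makes a random grouping an unlikely source of the gene count. For lists, 3 splits gave as many as 14 (highest other 14, median 5). That met the rule set beforehand against chance, fewer than 5 of 100 splits. Both others with 14 had a single KO and WT library exchanged. Splits that did not follow genotype thus also called lists at the preset correlation, and 0 lists passed with an estimated one. Although it met that rule, the list count therefore cannot exclude chance. The planned count-model tests were not run because of the floor at 1, and dropping the filter changed nothing since it removed 0 genes. Between 6.3% and 9.9% of the genes of a library lay at the floor, a share that did not follow depth (6.3% in KO replicate 5, with the fewest reads); 62% of simulated 2 fold changes were recovered, at 1 depth.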

Other observations

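Members of the dendritic cell list went in both directions. Cd209a, a lectin of monocyte-derived dendritic cells, rose to 7634 ± 1014 normalized counts in KO from 4154 ± 1182 in WT (SD, n = 5 and 4; limma adjusted p = 0.022), and the transcription factor gene Irf4 stood at 1874 ± 223 and 1050 ± 144 (adjusted p = 0.063). Clec9a, a receptor of cross-presenting dendritic cells, stood at 50.1 ± 32.2 and 411 ± 281 (adjusted p = 0.22), and Irf8, a factor that these cells need, at 3456 ± 546 and 5564 ± 1887 (adjusted p = 0.23). The list of 15 had 1 gene past the test over all genes and, adjusted over the list alone, 3 higher and 2 lower. In fry the list was past the threshold for change in either direction (adjusted p = 2.9e-05) and not for a common one (0.26). That result was not particular to dendritic cell genes. Many other lists passed it, among them neutrophil (fry adjusted p = 2.9e-05), macrophage identity (6.0e-04) and endothelial genes (6.0e-04).

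A few genes, singled out for this pattern after their values were seen, were highest in WT replicates 3 and 4. Gbp2, a guanylate-binding protein gene, stood at 41932 and 19518 normalized counts in these libraries, at 7420 and 8265 in WT replicates 1 and 2, and between 5815 and 8907 in KO. The chemokine gene Ccl5 stood at 20505 and 8216 against 3377 and 4467. Nos2 stood at 1266 and 599 against the floor in WT replicates 1 and 2. Of the 30 genes of the interferon list, 8 were higher in both of these libraries than in any of the other 7, and the remaining members were not. Both libraries belong to the 3 shallower ones, and the third, KO replicate 5, had 7864 of Gbp2, 2579 of Ccl5 and 109 of Nos2, where the other KO libraries had 6.9 or less of Nos2.

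Nnt stood at 3638 ± 881 in KO and 2205 ± 204 in WT (SD, n = 5 and 4; limma adjusted p = 0.12), while Ide and Entpd4, also picked after their values were seen, differed by -0.31 and 0.04 on the log2 scale. Ric3, the called gene within 10 Mb of Nucb2, was at the floor in each WT library and between 16.9 and 150 in KO. Lep, the leptin gene, stood at 45.7 ± 66.1 in KO and 331 ± 176 in WT (limma adjusted p = 0.17), while Adipoq, another adipocyte gene, stood at 35.0 ± 32.6 and 33.5 ± 32.0.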
